A study of Mus musculus with 14 samples.

How the data were processed

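The data set held 14 libraries of sorted cells from mouse epidermis at embryonic day 17.5, in 7 groups of 2: RNA-seq of wild-type and Pou4f3-mutant Merkel cells, ATAC-seq of wild-type Merkel cells, Pou4f3-mutant Merkel cells and wild-type touch dome epithelial progenitors, and CUT&RUN for ATOH1 and for POU4F3 in wild-type Merkel cells. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, Merkel cells were sorted for a green fluorescent reporter of Atoh1, RNA libraries were made with a single-cell RNA library kit, and CUT&RUN libraries carried molecular identifiers. The submitters' processing notes named STAR, RSEM, DESeq2, Bowtie2, MACS2 and UMI-tools and the mouse build mm10. Which tool was run on which assay, its version and its settings were not given in the sources used here.

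For RNA-seq, the authors deposited 1 table per library in the format RSEM writes, with an expected count, a TPM and an FPKM value per gene, per the file headers. An expected count is RSEM's estimate of the reads of a gene and need not be a whole number, so reads shared between paralogs or overlapping genes were split by the authors' model before deposit. The TPM and FPKM columns, which the authors scaled within each library, were not used here. Over all gene rows of a library, those with a count of 0 included, between 1.15% and 4.30% of the expected counts were not whole. The expected counts were rounded to whole numbers for all tests. Of 48709 gene rows, 48349 were paired with a symbol by their Ensembl identifier and 360 were kept by identifier alone. Reads of a gene and of an antisense partner were not separated, because strand use in counting was not given in the sources used here.

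For ATAC-seq and CUT&RUN, the authors deposited 1 narrowPeak list per library, the format MACS2 writes, so peaks had been called per sample and not on pooled samples. Each deposited peak carried a score, a fold enrichment at its summit over the caller's local background, and a −log10 p and −log10 q value. These are the authors' own values for each list, and they were used only to filter and rank peaks. The lowest deposited −log10 p in the 10 lists lay between 2.00 and 2.03. Whether a control library entered the CUT&RUN peak calls was not given in the sources used here. The POU4F3 list of library 2 differed in form from the other 9: its highest score was 1000 against 14542 to 484785 in the others, 104 of its peak numbers were skipped, and it held 0 peaks on contigs not placed on a chromosome.

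RNA counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by genotype, which left 11129 genes, libraries were scaled by TMM, and a quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest, two-sided) compared the genotypes without a replicate block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.686, a biological coefficient of variation of 0.828. DESeq2 1.42.0 was the alternative test, and its missing adjusted p-values were left missing. Gene lists were tested with camera in limma 3.58.1 on voom log2 values of the same counts, with a preset correlation between genes of 0.01, for the 22 of 28 lists with 5 or more tested members. An estimated correlation and fry, which tests whether the genes of a list move on balance in one direction, were alternatives. The edgeR step was tested on simulated data for this comparison: counts for the 11129 genes were drawn from the libraries' means and sizes, with 100 genes changed 8-fold and 100 changed 32-fold. At a dispersion of 0.05, 94.0% of the 8-fold and 96.0% of the 32-fold changes were recovered with 11 false calls, and at the dispersion of these libraries, 0.686, 0% of either were.

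The lists, fixed before the data were examined, were Merkel identity, vesicle release, granule and neuropeptide, amine and glutamate transport, channels, hair cell, neural transcription factors, axon and adhesion, Notch, hedgehog and touch dome, basal keratinocyte, suprabasal keratinocyte, hair follicle, fibroblast, melanocyte, endothelial, immune, erythroid, Schwann, sensory neuron, muscle, cell cycle, p53 and apoptosis, immediate early and stress, chromatin regulators, mitochondrial transcripts, ribosomal protein and histone genes. Named genes also followed a rule fixed before the data were examined: Pou4f3 and Atoh1 in every library, then the genes with the largest changes among those past the threshold, or, where fewer than 5 passed, the 10 genes with the smallest p as values only, and 3 members of the Merkel identity list by expression. The same rule fixed 12 loci: Atoh1, Pou4f3, Gfi1, Sox2, Isl1, Insm1, Lhx3, Krt8, Krt18, Krt20, Rab3c and Piezo2.

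Peaks with a −log10 q of at least 1.3 on placed chromosomes were merged within each library, and the merged peaks of the 6 ATAC libraries were joined into 282925 regions with a median width of 307 bp. A region counted as accessible in a library when it overlapped a peak by at least 1 bp. Regions were called Merkel-gained with a peak in both wild-type Merkel libraries and neither progenitor library, shared with a peak in all 4 of these libraries, and progenitor-only with a peak in both progenitor libraries and neither wild-type Merkel library. Merkel-gained regions with a peak in neither mutant library were called lost, and those with a peak in both were called kept. A factor was called bound where both of its CUT&RUN libraries had a peak. Strength was the lower of the wild-type Merkel −log10 q values of a region, and the regions accessible in both wild-type Merkel libraries were split into 10 strength bins of equal size. Odds ratios over regions were tested with Fisher's exact test and, across bins, combined by the Mantel-Haenszel method, with 95% intervals. Regions are not independent replicates, so these tests compare peak lists and not animals. On 20000 simulated regions with an odds ratio of 4 at equal strength, the bins recovered 3.50 (2.91 to 4.20), against 1.78 without bins. The simulated ATAC and POU4F3 lists of a group held the same regions, and strength carried no error, unlike these libraries. The simulation thus does not show how far bins remove differences in strength here. Peak lists were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

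Regions were assigned to the nearest of 21887 protein-coding RefSeq genes of GRCm38, the assembly behind mm10, within 100 kb of the gene body. The gene body took the place of the transcription start site named in the design, because the gene table gave no strand. Exons, introns and untranslated regions were not separated. Genes lower or higher at an unadjusted p under 0.05 took the place of genes past the adjusted threshold in the tests of genes near bound regions, because no gene passed it. Sequence motifs were not analysed here, because no genome sequence was used here.

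The alternatives were another count test, other scalings, other filters on low counts, a replicate block, a stricter peak threshold of 5, the same number of peaks per library (95588 for ATAC-seq and 77810 for CUT&RUN), another overlap rule, windows of 500 bp around summits, a peak in either CUT&RUN library, a shorter distance to genes of 25 kb, and the omission of each library in turn. With 1 library left in a group, that library was assumed to vary like the other group. Counting intervals of ratios at low counts cover counting error only.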

Results

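Merkel cells are mechanosensory cells of the skin that cluster in touch domes, and touch dome epithelial progenitors are the epidermal cells of the same structures. The measurements covered both cell types, sorted from mouse epidermis at embryonic day 17.5, with Merkel cells taken from wild-type and Pou4f3-mutant animals. Pou4f3 encodes a POU-domain transcription factor and Atoh1 a basic helix-loop-helix transcription factor of Merkel cells and inner ear hair cells. RNA-seq compared wild-type and mutant Merkel cells. ATAC-seq, which maps accessible chromatin, compared these cells and wild-type progenitors, and CUT&RUN, which releases DNA bound by a chosen protein, mapped ATOH1 and POU4F3 in wild-type Merkel cells. Each of the 7 groups held 2 libraries, and all 14 libraries were used.

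The RNA libraries held 2958153 and 1405889 expected counts in wild type 1 and 2, and 1041399 and 3902211 in the libraries labelled mutant 1 and 2. A count was found for 9642 genes in labelled mutant 1 and for 17319 to 17653 genes in the other 3 libraries. The mitochondrial ribosomal RNA mt-Rnr2 alone took 10.5% and 31.5% of the counts in wild type and 8.63% and 21.7% in the libraries labelled mutant. Log2 expression in labelled mutant 1 correlated across genes with the other libraries at 0.51 to 0.54, against 0.81 to 0.87 among those 3, with genes not being independent replicates. The ATAC lists held 195489 and 221549 peaks in wild-type Merkel cells, 135026 and 159513 in mutant Merkel cells, and 168271 and 178696 in progenitors. The CUT&RUN lists held 97958 and 119788 peaks for ATOH1 and 141925 and 134202 for POU4F3. Read depths behind the peak lists are not known. Replicates are not said to come from separate animals or litters, so p-values measure only the spread between these samples, which may be technical. With 2 libraries against 2, a two-sided exact permutation test cannot go below p = 0.333, so region counts are given without a test over libraries.

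The first comparison asked which chromatin is accessible in Merkel cells and not in the progenitors beside them. Of 120100 regions accessible in both wild-type Merkel libraries, 55778 had a peak in neither progenitor library and 54501 had a peak in both. The reverse class, accessible in both progenitor libraries and neither wild-type Merkel library, held 24662 regions. The 12 loci fixed in advance, of genes that mark or equip Merkel cells, lay on both sides of the overall share, 55778 of 120100. All of them had some Merkel-gained regions. Piezo2, the mechanically gated channel of touch, had 21 of them among 33 accessible regions, and Rab3c, a GTPase of secretory vesicles, had 17 of 25. Sox2, a transcription factor of Merkel cells, had 15 of 21, and Pou4f3 had 12 of 17. Fewer lay near Isl1, a LIM-homeodomain transcription factor, with 5 of 10, and near Atoh1, with 3 of 9. The keratin genes Krt20, Krt8 and Krt18, whose products mark Merkel cells in the skin, had 3 of 4, 2 of 3 and 1 of 5. Lhx3, Gfi1 and Insm1, which encode further transcription factors, had 5 of 7, 4 of 7 and 2 of 4. Of the shared regions, 22.0% lay within 1 kb of a gene end, against 3.23% of the progenitor-only regions. Without wild-type Merkel library 1 the Merkel-gained count was 85013, and with the same number of peaks per library it was 33229. Without progenitor library 1 or 2 the progenitor-only count was 46439 or 40591.

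The mutant ATAC libraries were then set against these classes, to ask which Merkel-gained chromatin was accessible in the libraries labelled Pou4f3 mutant. Of the 55778 Merkel-gained regions, 28194 (50.5%) had a peak in neither mutant library, 11461 (20.5%) had a peak in 1, and 16123 (28.9%) had a peak in both. Of the shared regions, 21.1% had a peak in neither mutant library and 59.7% in both. Progenitor-only regions stayed without peaks in the mutant Merkel cells, with 94.4% in neither library and 0.491% in both, and 2357 regions were accessible in both mutant libraries alone. Taken singly, mutant libraries 1 and 2 lacked a peak in 63.1% and 58.5% of Merkel-gained regions (SD 3.24, n = 2) and in 30.1% and 31.2% of shared regions (SD 0.767, n = 2). The odds of lacking a peak in both mutant libraries were 3.83 times higher for Merkel-gained than for shared regions (95% interval 3.73 to 3.93, Fisher's exact test) and 2.52 times higher within bins of equal wild-type strength (2.44 to 2.59). With the same number of peaks taken from each library the shares were 36.3% and 10.8% and the odds ratio over bins was 3.67 (3.52 to 3.82). At that number of peaks, regions gained in wild-type library 1 lacked a peak in wild-type library 2 in 21.9% and in mutant libraries 1 and 2 in 54.9% and 52.5%, and shared regions in 7.76%, 21.7% and 24.6%. The odds ratio of gained against shared regions over bins was thus already 1.96 (1.87 to 2.06) in wild-type library 2, against 3.30 (3.20 to 3.41) and 2.39 (2.31 to 2.47) in mutant libraries 1 and 2. With regions defined by wild-type library 2 it was 1.47 (1.40 to 1.54) in wild-type library 1, against 3.03 (2.93 to 3.13) and 2.19 (2.12 to 2.26).

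**Figure D1:**
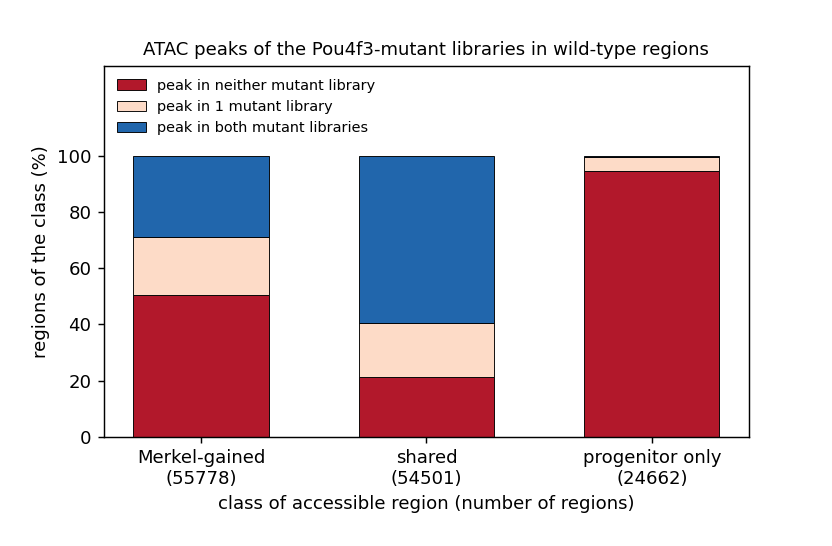
Share of Merkel-gained, shared and progenitor-only regions, in percent on the vertical axis, with an ATAC peak in neither (red), 1 (pale) or both (blue) mutant Merkel libraries. The red share was 50.5% for Merkel-gained, 21.1% for shared and 94.4% for progenitor-only regions.

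The CUT&RUN lists show where ATOH1 and POU4F3 bound in wild-type Merkel cells. Both libraries of a factor had a peak in 17397 regions for ATOH1 and in 11947 for POU4F3. POU4F3 regions overlapped 14.3% of the ATOH1 regions, and ATOH1 regions overlapped 22.6% of the POU4F3 regions. With POU4F3 regions moved by 10 kb, 0.514% of the ATOH1 regions overlapped. Of the ATOH1 regions, 90.6% lay in chromatin accessible in wild-type Merkel cells, 45.3% in Merkel-gained and 40.2% in shared regions. Of the POU4F3 regions, 68.7% lay in accessible chromatin, 49.9% in Merkel-gained and 15.2% in shared regions. Within accessible regions of equal strength, the odds of POU4F3 binding were 2.90 times higher where ATOH1 was bound (95% interval 2.74 to 3.06). The 4 pairs of single libraries gave 6.23% to 12.3% (SD 2.82) of ATOH1 peaks overlapping POU4F3. Of the peaks in POU4F3 libraries 1 and 2, 8.97% and 9.50% overlapped the other POU4F3 list, and for ATOH1 these shares were 22.1% and 14.2%, against 82.7% and 75.4% for wild-type Merkel ATAC. Among peaks with a −log10 q of at least 5 the shares were 23.8% and 35.7% for POU4F3 and 90.7% and 18.9% for ATOH1. The 14.3% became 3.81% without ATOH1 library 1, 3.51% without ATOH1 library 2, 19.7% without POU4F3 library 1 and 34.6% without POU4F3 library 2.

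Binding was next compared between Merkel-gained regions lost and kept in the mutant. POU4F3 peaks lay in 11% of lost and 9.3% of kept regions, a small difference (odds ratio 1.21, 95% interval 1.13 to 1.29, Fisher's exact p = 1.45e-08). ATOH1 peaks lay in 5.57% of lost and 31.1% of kept regions (odds ratio 0.130, 0.123 to 0.139, Fisher's exact test). Kept regions were the stronger ones in wild type and stronger regions had more peaks of either factor, so the comparison was repeated at equal wild-type strength. There the odds ratio for POU4F3 was 5.89 (5.36 to 6.48, Mantel-Haenszel over 10 bins), with values from 2.51 to 10.4 in the single bins. In the strongest bin, 69.5% of lost and 31.4% of kept regions had POU4F3 peaks. For ATOH1 it was 0.385 (0.359 to 0.413), with 0.283 to 0.417 in the single bins. The bins were planned before the data were examined, but their combination into 1 ratio was added after the data had been seen. The crude POU4F3 ratio turned below 1 without some libraries, to 0.974 without POU4F3 library 1, 0.770 without wild-type ATAC library 1 and 0.804 without wild-type ATAC library 2, whereas over bins these settings gave 2.63, 5.85 and 5.18.

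Wild-type library 2 served to show how often such regions are missed by chance. Among regions gained in wild-type library 1 at equal numbers of peaks, POU4F3-bound regions lacked a peak in wild-type library 2 less often than others of equal strength (odds ratio 0.427, 0.371 to 0.491) and more often in mutant libraries 1 and 2 (3.79, 3.51 to 4.09, and 3.89, 3.61 to 4.2). ATOH1-bound regions lacked a peak less often than others in wild-type library 2 (0.289, 0.249 to 0.335) as well as in the mutant libraries (0.446 and 0.415). With regions defined by wild-type library 2 the ratios for ATOH1 were 0.502 (0.443 to 0.569) in wild-type library 1 and 0.497 and 0.446 in the mutant libraries, and those for POU4F3 were 0.692 (0.612 to 0.781), 4.35 and 4.43.

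Regions grouped by both factors, a grouping chosen after the data had been seen, differed in how often they were lost. Regions with POU4F3 in both of its libraries and not ATOH1 had a peak in neither mutant library in 70.5% of 3590 cases, and regions with ATOH1 and not POU4F3 in 16.8% of 5934. Regions bound by both factors were lost in 30.5% of 1872 cases and the remaining 44382 regions in 54.3%. At equal strength, the odds of loss relative to these remaining regions were 6.94 times as high with POU4F3 and not ATOH1 (6.13 to 7.85), 0.326 times as high with ATOH1 and not POU4F3 (0.300 to 0.355), and 2.02 times as high with both (1.76 to 2.33). Among ATOH1-bound regions, those that also had POU4F3 peaks had odds of loss 6.75 times as high (5.70 to 8). When 22726 regions with a peak in only 1 library of a factor were left out, 80.8% of 1973 regions with POU4F3 and no ATOH1 peak were lost, 14.6% of 3801 with ATOH1 and no POU4F3 peak, and 59.7% of 25406 with no peak of either.

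**Figure D2:**
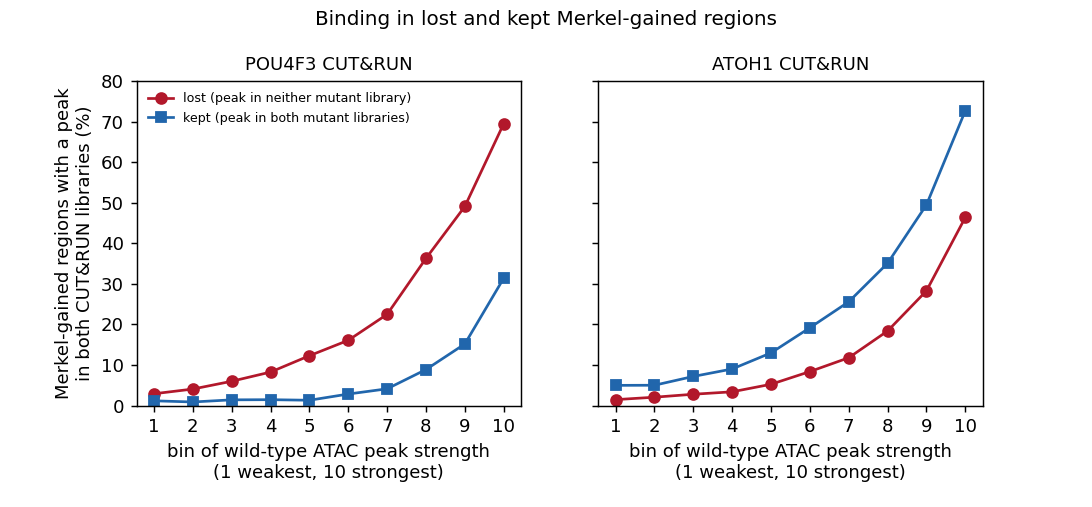
Percent of lost (red circles) and kept (blue squares) Merkel-gained regions with CUT&RUN peaks in both libraries, for POU4F3 (left) and ATOH1 (right), against 10 bins of wild-type ATAC peak strength from weakest to strongest. POU4F3 peaks were more frequent in lost regions in all 10 bins, from an odds ratio of 2.51 to one of 10.4, and ATOH1 peaks were less frequent in all 10.

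At single loci these classes lay side by side. Krt20 (chromosome 11, 99428385 to 99438153, mm10) had a Merkel-gained region across the higher-coordinate edge of its gene body. Without strand in the gene table, this edge was not read as the start or the end of transcription. The region, at 99437854 to 99438612, had ATOH1 and POU4F3 peaks in all 4 CUT&RUN lists and no peak in either mutant library. A second such region, 99449027 to 99449845, 10873 bp from the gene, had −log10 q values of 53.2 and 77.1 in wild type, 1.60 in mutant library 1 and no peak in mutant library 2. Near Isl1 (chromosome 13, 116298270 to 116309688), 4 of 5 Merkel-gained regions were lost and none was kept, and all 3 with POU4F3 peaks were among the lost. These 3 lay at 116256125 to 116256992, at 116280774 to 116281158 and, inside the gene, at 116299748 to 116300153. The Piezo2 locus (chromosome 18, 63010213 to 63387716) lost 14 of 21 Merkel-gained regions, including 1 inside the gene with POU4F3 and ATOH1 peaks at 63069309 to 63070033. A stronger region of Piezo2 bound by both factors, 63312902 to 63313685, was kept, with −log10 q of 88.9 and 145 in wild type and of 7.83 and 8.64 in the mutant. The authors' q values were set per list, so their sizes are not comparable between libraries.

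Other regions with both factors were accessible in the mutant. A region 91683 bp from Atoh1 (chromosome 6, 64822929 to 64823874) had ATOH1 and POU4F3 peaks in all 4 lists and peaks in both mutant libraries. Around Pou4f3 itself (chromosome 18, 42394597 to 42396093), 5 of 12 Merkel-gained regions were lost and 5 kept, and the 3 bound by POU4F3 were all kept. Krt8 and Krt18 kept all 3 of their Merkel-gained regions. Sox2 lost 9 of 15 and Rab3c lost 7 of 17, with 1 POU4F3-bound region lost at Rab3c. Of 5 Merkel-gained regions at Lhx3 none was lost, and Gfi1, Insm1 and Atoh1 lost 2 of 4, 1 of 2 and 1 of 3. These counts per locus are too small for a test.

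**Figure D3:**
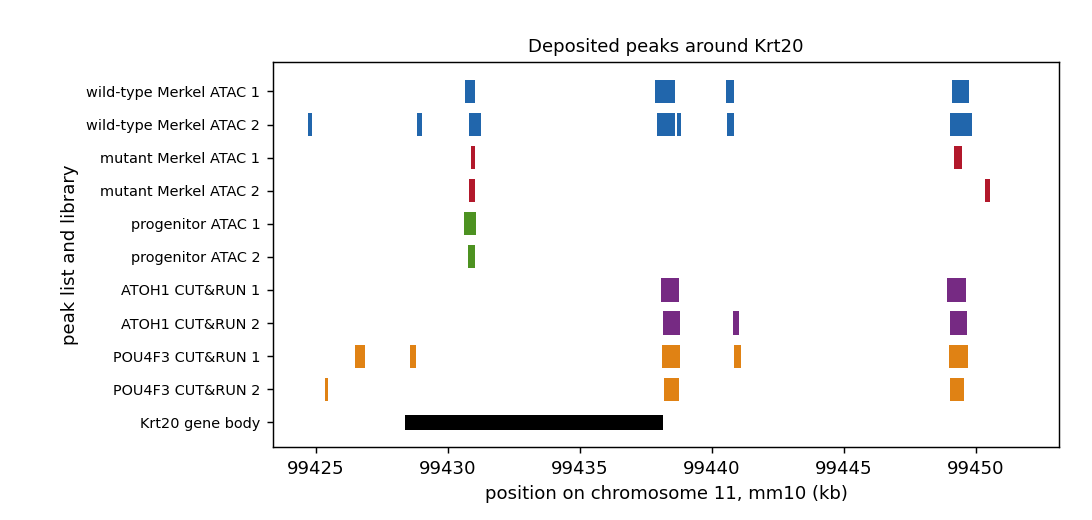
Deposited peaks (bars) of the 10 ATAC and CUT&RUN lists around Krt20 on chromosome 11, with position in kb (mm10) on the horizontal axis, 1 row per library and the gene body in black. The region from 99437854 to 99438612 has peaks in the wild-type Merkel ATAC, ATOH1 and POU4F3 rows and none in the mutant or progenitor rows.

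RNA-seq compared transcript levels between wild-type Merkel cells and the libraries labelled mutant. Pou4f3 itself was not lower in the latter, with 2475 and 893 counts in wild type and 2102 and 2641 in the libraries labelled mutant. Its scaled values were 711.7 and 622.1 CPM (counts scaled by TMM to a common library size) in wild type and 3114 and 552.3 CPM in the libraries labelled mutant, a log2 difference of 1.46 (SE 1.54). Gene-level counts do not check the deleted part of the gene, since the allele was not given in the sources used here. Atoh1 had 497.5 and 340 CPM in wild type and 1668 and 326.4 in the libraries labelled mutant, a log2 difference of 1.25 (SE 1.41). Without labelled mutant 1 the log2 differences of Pou4f3, Atoh1 and Isl1 changed sign, to −0.26, −0.35 and −0.64.

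Of 11129 genes, 0 passed edgeR's test, with 367 at an unadjusted p under 0.05 (317 higher and 50 lower in the libraries labelled mutant, 556 expected by chance), and DESeq2 called 58. Of the 58, 46 were higher and 12 lower, 3668 genes had no adjusted p, and in 44 both libraries labelled mutant lay beyond both wild-type libraries. The genes with the smallest p are given as values. Lower in both libraries labelled mutant were Krt20 (280 and 185 counts in wild type, 1 and 12 in labelled mutant), the bicarbonate transporter gene Slc4a4 (382 and 316 against 1 and 9), Cntnap2, a neurexin-like adhesion gene (177 and 98 against 0 and 4), and Aspa, which encodes aspartoacylase (121 and 165 against 0 and 1). Higher in both were the neuronal microtubule gene Dcx (2 and 0 against 237 and 362), the transcription factor genes Helt (7 and 2 against 173 and 397) and Ebf2 (6 and 5 against 210 and 533), Clic6 (1 and 2 against 184 and 172), Clmp (15 and 4 against 133 and 392) and Fstl5 (31 and 10 against 290 and 507). The log2 differences were −5.58 (SE 1.25) for Krt20, −6.52 (1.25) for Slc4a4, −6.47 (1.55) for Cntnap2, 6.56 (1.28) for Helt, 6.36 (1.26) for Ebf2, 5.25 (1.19) for Clmp and 5.06 (1.22) for Fstl5. With so few counts in 1 group, the scaled ratios with counting intervals were 270 (74.3 to 2230) for Dcx and 107 (36.3 to 521) for Clic6, higher in the libraries labelled mutant, and 318 (56.6 to 12600) for Aspa, higher in wild type. All 10 had an adjusted p of 0.9999 in edgeR and of 0.000212 to 0.00768 in DESeq2. Of the most abundant Merkel identity genes, Krt8 and Snap25, a gene of the vesicle fusion machinery, had log2 differences of 1.02 (SE 1.34) and 2.66 (SE 1.28), and Isl1 of 0.67 (SE 1.24).

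Omitting either library labelled mutant moved the number of calls. edgeR called 74 genes without labelled mutant 1, 51 higher and 23 lower, and 4846 without labelled mutant 2, 1767 higher and 3079 lower. The 74 included Eef1a2, mt-Co3 and Xist, for which labelled mutant 2 stood apart from the other 3 libraries and which were chosen after their values were seen. It called 0 without either wild-type library, and 42 with no filter on low counts. The median log2 difference of all tested genes was −0.24, and both libraries labelled mutant lay above both wild-type libraries for 9.95% of genes and below for 17.1%, where chance gives 16.7% for each.

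**Figure D4:**
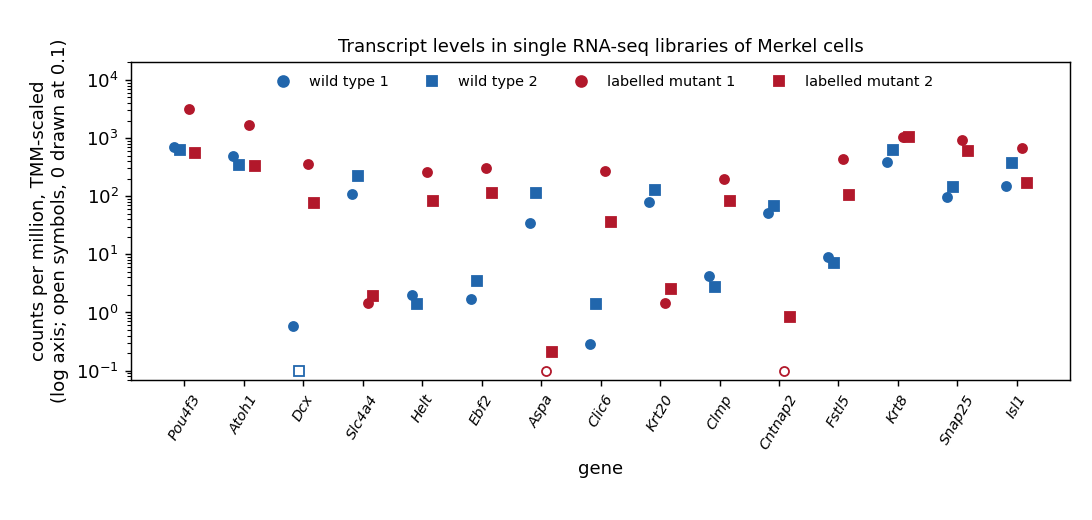
CPM, counts scaled by TMM to a common library size, on a log axis, of 15 named genes in the 4 RNA libraries, with wild type in blue, libraries labelled mutant in red, and open symbols drawn at 0.1 for a count of 0. Pou4f3 stood at 3114 in labelled mutant 1 and at 552.3 to 711.7 in the other libraries, and Krt20 and Slc4a4 were lower in both libraries labelled mutant.

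Of 22 gene lists tested, 6 passed camera's adjusted threshold with the preset correlation and 0 with an estimated correlation or with fry. In the lists below, the absence of members passing over all genes says little. At the dispersion of these libraries, 0.686, edgeR recovered 0% of simulated 32-fold changes. Neural transcription factor genes were higher in the libraries labelled mutant (adjusted p = 1.94e-11 in camera, adjusted p = 0.924 with an estimated correlation). In 15 of the 27 members measured, both libraries labelled mutant lay above both wild-type libraries, and in 3 below. No member passed over all genes and 2 passed adjusted over the list alone, Ebf2 and Nhlh2, a neuronal helix-loop-helix gene with 0 counts in both wild-type libraries and 36 and 107 in the libraries labelled mutant. Sox11 (128 and 54 against 667 and 643 counts) and Neurod1 (12 and 14 against 26 and 415), both of neuronal differentiation, had log2 differences of 3.91 (SE 1.40) and 3.27 (SE 1.25). This list passed without each of the 4 libraries in turn, and labelled mutant 1 had the highest summed level, 11050 CPM against 2037 to 2315.

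Keratinocyte genes were lower in the libraries labelled mutant. The suprabasal list (adjusted p = 7.99e-06 in camera, adjusted p = 0.924 with an estimated correlation) had both libraries labelled mutant below wild type in 10 of 22 members. Among them were Krt1 and Krt10, keratins of differentiated epidermis. Scaled Krt1 stood at 37600 and 8960 CPM in wild type and at 1630 and 5550 in the libraries labelled mutant. For Krt10 the values were 14800 and 7970 against 1880 and 5190. The basal list (adjusted p = 0.00255, adjusted p = 0.924 with an estimated correlation) had 10 of 19 below and none above, among them Krt5, Krt14 and Col17a1 with log2 differences of −1.37 (SE 1.40), −1.38 (SE 1.45) and −1.80 (SE 1.38). No member of either list passed over all genes or adjusted over the list alone. Without wild type 1 the suprabasal list did not pass (adjusted p = 0.591 in camera), and the basal list passed without each library. These are markers of the epidermal cells around Merkel cells, and summed suprabasal levels ranged from 4747 to 56380 CPM over the 4 libraries.

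The remaining lists that passed did not pass when particular libraries were omitted. Ribosomal protein genes were higher (adjusted p = 3.00e-05 in camera, 0.924 with an estimated correlation) but lower without labelled mutant 1 (adjusted p = 0.139), whose summed level was 106100 CPM against 16850 to 18420. Fibroblast genes were higher (adjusted p = 0.000281, adjusted p = 0.924 with an estimated correlation), with an adjusted p of 0.630 without wild type 1 and of 0.576 without labelled mutant 2, but of 5.66e-23 without labelled mutant 1 and 1.1e-09 without wild type 2. In the latter fits the endothelial list (adjusted p = 2.79e-07 and 7.44e-05 in camera) and the erythroid list (adjusted p = 4.78e-09 and 5.18e-07) were also higher. Summed levels in wild type 1 and 2 and labelled mutant 1 and 2 were 441.4, 1269, 961.3 and 2534 CPM for fibroblast genes, 0.2876, 13.93, 0 and 13.17 for endothelial genes and 5.464, 113.6, 170.3 and 128.6 for erythroid genes. Of 15 fibroblast members measured, 0 passed over all genes and 1 adjusted over the list alone, the growth factor receptor gene Pdgfra (4 and 7 against 208 and 118 counts). Cell cycle genes were lower (adjusted p = 0.0172, adjusted p = 0.924 with an estimated correlation), with an adjusted p of 0.407 without labelled mutant 1 and 0.138 without labelled mutant 2. No cell cycle or ribosomal protein gene passed over all genes or adjusted over the list alone.

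The Merkel identity list did not pass (adjusted p = 0.802 in camera), with both libraries labelled mutant above wild type in 3 and below in 6 of 19 members. Of these, 0 passed over all genes and 2 adjusted over the list alone, both lower: Krt20 and Piezo2 (575 and 375 against 5 and 65 counts). Without labelled mutant 1 the list was lower (adjusted p = 0.0111 in camera). The vesicle release (adjusted p = 0.883), channel (0.802), hair cell (0.802), axon and adhesion (0.802) and sensory neuron (0.802) lists did not pass in camera. In these, 0 members passed over all genes, and adjusted over the list alone 1 passed for vesicle release (the synaptic vesicle gene Sv2c, lower), 1 for channels (Piezo2, lower), 2 for hair cell (the transcription factor gene Barhl1, higher, and the myosin gene Myo15, lower), 1 for axon and adhesion (Cntnap2, lower) and 1 for sensory neuron (Avil, which encodes an actin-binding protein, lower). These members fall outside the rule for named genes and were chosen after their values were seen. No member passed, over all genes or adjusted over the list alone, in the lists for granule and neuropeptide (adjusted p = 0.614 in camera), Notch (0.960), hedgehog and touch dome (0.305), hair follicle (0.802), melanocyte (0.802), p53 and apoptosis (0.883), immediate early and stress (0.802), chromatin regulator (0.614), mitochondrial transcript (0.326) and histone (0.960) genes. Median, mean and camera direction differed in sign for the Merkel identity, channel, hair cell, Notch, hair follicle and histone lists. The amine and glutamate, endothelial, immune, erythroid, Schwann and muscle lists had 4, 1, 2, 4, 3 and 0 members with enough counts when all 4 libraries were used and were not tested there, and no member of theirs passed.

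Genes near regions bound by POU4F3 and lost in the mutant were then compared with all others. The 1174 such genes tested had a median log2 difference of −0.33, against −0.24 for all genes, and did not differ as a set (camera p = 0.392, adjusted p = 0.653 over the 10 region gene sets, p = 0.768 with an estimated correlation). Among them 22 (1.87%) were lower at an unadjusted p under 0.05, against 0.281% of other genes, an odds ratio of 6.77 (3.68 to 12.3, Fisher's exact p = 1.30e-09). The share of higher genes was 3.07% against 2.82% (odds ratio 1.09, 0.743 to 1.55). Over all genes, 50 were lower and 317 higher at this p, 367 in all, against 556 expected by chance. With fewer genes than chance gives, no single gene among the 22 can be taken as lower. The ratio compares shares only. Genes near kept regions bound by POU4F3 had a similar ratio for lower genes, 7.67 (3.93 to 14.4), genes near lost regions bound by both factors 11.2 (5.10 to 22.5), and genes near lost regions without POU4F3 3.34 (1.81 to 6.4). Near progenitor-only regions the ratio was 1.22 (0.670 to 2.21). Near kept regions as a whole the ratio was 2.67 (1.47 to 4.97) for lower and 1.36 (1.08 to 1.72) for higher genes. The use of unadjusted p and of the nearest gene body was chosen after the data had been seen. The gene sets overlap and their ratios were not tested against each other, and the libraries labelled mutant were not lower for Pou4f3 itself.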

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

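Peaks on contigs not placed on a chromosome entered no comparison. Summed over the 10 peak lists they numbered 891, above the 3 that a count of 0 allows, and made up 0.0574% of the 1552417 deposited peaks. They were found in 9 lists, at 61 to 144 each, and the POU4F3 list of library 2 held 0.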

How the results depend on the processing

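Of 97 alternative values for the results that answer a comparison, 71 counted as the same, 22 moved, 1 was weaker, 1 stronger and 2 reversed. The same did not mean unchanged. Against 55778 Merkel-gained regions, 40400 at a −log10 q of at least 5 counted as the same. So did 76811 without wild-type Merkel ATAC library 2. For the count of changed genes, 0 by edgeR's quasi-likelihood test, DESeq2 gave 58 and no filter on low counts gave 42. Other scalings, a stricter filter and a fold threshold gave 0, and omitting each library in turn gave 0 to 4846. The replicate numbers were not taken to pair the RNA libraries: deviations of same-numbered libraries correlated at 0.112 over 11129 genes, and the replicate block gave 1 changed gene, Dcx (adjusted p = 0.00226 in edgeR). The 6 gene lists past the threshold became 0 with an estimated correlation and 0 with fry, and 7 with scaling by library totals, where mitochondrial transcripts also passed. With libraries omitted 4 to 9 lists passed, which were not the same lists: endothelial, erythroid, histone, mitochondrial transcript and Merkel identity genes were among them.

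The count of Merkel-gained regions was 33229 with equal numbers of ATAC peaks, where fewer peaks enter by construction, and 55845 to 85013 with libraries omitted. Progenitor-only regions ranged from 24687 to 46439 with libraries omitted, where fewer lists have to hold or lack a peak. The lost share of Merkel-gained regions, 50.5%, was 58.0% at a −log10 q of at least 5, 36.3% with equal numbers of peaks, 71.1% when regions with a peak in 1 mutant library were added, and 49.7% to 63.1% with libraries omitted. The cause of the first of these was not tested. The lost share of shared regions rose there too, from 21.1% to 26.8%, so the rise was not particular to Merkel-gained regions. The overlap rule for shorter peaks could not change these counts, because each peak lies within its merged region. They are nonetheless among the 71 values counted as the same.

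The POU4F3 odds ratio without strength bins was 1.02 (Fisher's exact p = 0.552) under the stricter overlap rule, and 0.974 to 1.23 with CUT&RUN libraries omitted, reversed at 0.974 without POU4F3 library 1, and the cause was not tested. Over bins it was above 1 under every alternative run, at 2.63 to 3.99 with CUT&RUN libraries omitted. For ATOH1 the ratio was 0.177 to 0.178 and over bins 0.378 to 0.457 with ATOH1 libraries omitted. The share of ATOH1 regions with POU4F3 ranged from 3.51% to 34.6% with libraries omitted, where a single list replaces the regions common to a pair of lists. The median log2 difference of genes near POU4F3-bound lost regions was −1.19 to −0.0738 with RNA libraries omitted, where the −1.19, without labelled mutant 2, stands beside a median of −1.11 for all genes. Without wild type 1 it was −0.378 and the set, which otherwise did not pass camera, passed 0.05 before adjustment. Without wild type 2 it was −0.108 and the camera direction reversed without passing. The cause of either was not tested.

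Of 120 alternative values for named genes, 83 stayed on the same side of the threshold and 3 changed sign without labelled mutant 1. The rest passed it, 10 under DESeq2, 1 under the replicate block and the others in fits with 1 library labelled mutant left. Of the 15 named genes, 10 were chosen for the smallest p in these same libraries. Their passing is therefore no separate support. The alternatives for genes near bound regions that omit RNA libraries or use the block, the single odds ratios over all bins for POU4F3 and ATOH1, and the binding classes, were chosen after seeing the data. Motif alternatives were not run, and the depth of reads behind the peak lists, which limits weak regions, is not known.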

Other observations

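The region counts per gene list, the genes called with each labelled mutant library alone, and the tests of progenitor cells, chance misses of gained against shared regions, background cleavage, chance misses of ATOH1-bound regions and swapped labels were chosen only after the results were seen.

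Regions accessible in Merkel cells and not in progenitors were unevenly spread over the gene lists. Compared with shared regions, Merkel-gained regions were more often assigned to axon and adhesion genes (786 regions, odds ratio 2.63, 95% interval 2.3 to 3), such as the neurexin and contactin genes, and to hair cell genes (198 regions, 1.98, 1.55 to 2.52), which serve another mechanosensory cell. Genes of neural transcription factors (1.79, 1.43 to 2.23), Merkel identity (1.71, 1.32 to 2.21), channels (1.71, 1.42 to 2.05) and vesicle release (1.69, 1.37 to 2.08) also had more, with Fisher's exact p adjusted over 25 lists of 7.59e-05 or less. So had melanocyte genes (2.24, 1.39 to 3.62, adjusted Fisher's exact p = 0.00141) and granule and neuropeptide genes (1.75, 1.29 to 2.39), whereas sensory neuron (1.26, 0.865 to 1.83) and amine and glutamate transport genes (1.08, 0.694 to 1.69) did not pass. Fewer lay near basal keratinocyte (0.362, 0.266 to 0.494), cell cycle (0.330, 0.204 to 0.536) and immediate early and stress genes (0.305, 0.209 to 0.446). Shared regions lay within 1 kb of a gene end in 22.0%, lost and kept Merkel-gained regions in 2.25% and 2.18%. Progenitor-only against shared regions gave 1.29 for axon and adhesion and 0.578 for cell cycle genes, but 1.04 for hair cell and 1.20 for basal keratinocyte genes. The part of location was not tested. These tests treat regions as independent although many lie at the same gene, so a few genes with many regions can carry a list. The 786 axon and adhesion regions lay near 32 genes at most. Lists also share members, such as Pou4f3 and Atoh1, so they are not separate findings. The share of Merkel-gained regions lost in the mutant ran from 27.3% near cell cycle genes to 63.6% near Schwann genes, with 44.1% near Merkel identity genes. At equal strength, immediate early and stress genes alone passed adjustment over the lists, with 10 of 35 regions lost (odds ratio 0.333, 0.157 to 0.703, adjusted p = 0.0426 over regions, not samples).

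Each library labelled mutant was also set alone against the pair of wild-type libraries in edgeR. With the same sign in both comparisons, 37 genes were called, 20 higher and 17 lower. In 20 simulated data sets with no change that share the wild-type libraries the overlap was 0. They were drawn at a dispersion of 0.686, at which the edgeR test recovered 0% of simulated 32-fold changes with 0 false calls. An overlap of 0 was thus close to fixed in advance and gives no support to the shared genes. Independent lists would share 3.81 higher and 6.54 lower among 10835 genes. Part of the excess over that may come from the shared wild-type libraries. Among the lower genes were Piezo2, Krt20, Sv2c (675 and 293 counts in wild type, 0 and 35 in labelled mutant), Avil (574 and 290 against 0 and 31) and the stereocilia myosin gene Myo15 (81 and 29 against 0 and 0). Among the higher were the neuronal and neuroendocrine transcription factor genes Neurod1 (12 and 14 against 26 and 415), Nkx2-2 (5 and 0 against 19 and 117), St18 (20 and 18 against 60 and 464) and Nhlh2, and the granule protein gene Chgb (38 and 50 against 75 and 785).

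More Merkel-gained than shared regions lacked a peak in the mutant libraries. With equal numbers of peaks this contrast remained, with an odds ratio over strength bins of 3.67. This test cannot exclude fewer peaks called in the mutant as the account. At equal numbers a left-out wild-type library also exceeded 1, at 1.96 and 1.47. Progenitor cells in the mutant sort would bring progenitor-only regions, of which 0.491% had peaks in both mutant libraries. Chance misses near the calling limit stay open: gained regions were missed in the mutant libraries at least 30.6 percentage points more often than in wild-type library 2, but shared regions were missed more often too, and the odds ratio of gained against shared regions was 1.96 in wild-type library 2 itself. It was 3.30 and 2.39 in the mutant libraries. The step from wild-type library 2 to the lower of these, taken as a ratio, was smaller than that between the mutant libraries. With regions defined by wild-type library 2, wild-type library 1 stood at 1.47 and the mutant libraries at 3.03 and 2.19. There the step to the lower mutant value was the larger one, so the definitions did not give the same answer. A need of Merkel-gained chromatin for Pou4f3, a delay in maturation and unknown read depths also stay open and were not tested.

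At equal strength POU4F3 peaks marked lost regions (odds ratio 5.89) and ATOH1 peaks marked kept regions, so cleavage of open chromatin without a bound factor, which would move both factors to the same side, is argued against. Chance misses are argued against for POU4F3, because its regions were missed less often than others in wild-type library 2 (odds ratio 0.427). For ATOH1 the ratio was 0.289 in wild-type library 2, against 0.446 and 0.415 in the mutant libraries, but 0.502 in wild-type library 1, against 0.497 and 0.446, when wild-type library 2 defined the regions, so chance misses stay open for its lower share among lost regions, which weakens the argument against cleavage. A hypothesis left by these tests is that regions bound by POU4F3 depend on it for accessibility, directly or through other factors. The POU4F3 lists overlapped little. The odds ratio over bins was 2.63 without POU4F3 library 1, 3.99 without POU4F3 library 2 and 2.99 with a peak in either CUT&RUN library. Why the lists overlapped so little was not tested.

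Pou4f3 transcripts were not lower in the libraries labelled mutant. Genes near POU4F3-bound lost regions were over-represented among the genes lower at an unadjusted p under 0.05 (odds ratio 6.77). They were not among the higher genes, which a swap of all genotype labels would predict (1.09, 0.743 to 1.55). At this p, 367 genes were found in all, against 556 expected by chance. Krt20, which had lost regions in the mutant ATAC libraries, was lower in both RNA libraries labelled mutant. Isl1, with 3 POU4F3-bound lost regions, was not: it had 152 and 371 CPM in wild type and 667 and 166 in the libraries labelled mutant. Over-represented among the lower genes too were genes near POU4F3-bound kept regions (7.67), ATOH1-bound lost regions (7.43) and lost regions without POU4F3 (3.34), though these ratios were not tested against each other, and a swap stays open. The shift of these 1174 genes as a set (adjusted p = 0.653 in limma's camera, 0.392 before adjustment) did not tell whether single libraries carry a wrong label. An allele that is transcribed without giving a working protein is an untested candidate explanation.

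Some genes stood apart in single RNA libraries. The mitochondrial gene mt-Co3 had 3295 and 553.8 counts in wild type, 1231 in labelled mutant 1 and 0.08 in labelled mutant 2. Eef1a2, a translation elongation factor gene, had 0 counts in 3 libraries and 511 in labelled mutant 2. Whether annotation or alignment differed for this library was not tested, so these values are not read as expression, and the genes are among the 74 called without labelled mutant 1. Xist, which is transcribed from the inactive X chromosome of females, had 2361 and 520.4 counts in wild type. It had 597.0 in labelled mutant 1 and 1 in labelled mutant 2. The Y-linked gene Ddx3y had 33 and 65 in wild type and 4 and 196 in labelled mutant 1 and 2. By these genes the libraries did not hold the same mix of sexes. Its part in the differences between genotypes was not tested.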
